A study of Mus musculus with 16 samples.

How the data were processed

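The samples were 16 arrays of CD48-KSL cells sorted from cultures of C57BL/6 CD34-KSL stem cells, each culture having received 2C9.G2 or control IgG in SCF, TPO or both. Per the labels' protocols, RNA was amplified with the Ovation aminoallyl kit, labelled with Cy3 and hybridized to a 1-colour whole mouse genome array (design 014868, probe positions in build mm7). The deposited scanner files hold spot intensity from Agilent Feature Extraction. Per the file headers this was version 10.7.3.1, while the submitters' processing notes name 9.5.3. Per the file headers the intensity had spatial detrending, background subtraction and multiplicative detrending within the array and no scaling between arrays. The deposited value table holds log2 values of 33842 probes, 15437 of them complete. By comparison with the scanner files these were quantile normalized, centred per probe and blank where not well above background (median absolute difference from such values 0.011), with column medians from 0.064 to 0.171.

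Each array had 45018 spots, of which 1639 were controls and 43379 were not, for 41174 probes. Probe names matched current mouse RefSeq symbols for 22951 probes, and the other 18223 kept the names in the files. The reference table served for symbols only. There were 0 saturated spots and at most 127 outlier spots on an array. Precision was limited by signal over background: 51.7 to 62.7% of probes were well above background, and the 75th percentile of an array ran from 150.2 to 268.1 intensity units. By their headers the arrays came from 5 slides scanned on 1 day. Slide 1 held 3 SCF+TPO IgG arrays and 1 SCF+TPO 2C9.G2 array, slide 2 held 2 TPO IgG and 2 SCF+TPO 2C9.G2 arrays, and the other slides held 1 group each. The first 2 principal components took 13.3% and 10.2% of the variance.

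Log2 processed intensity minus the 75th percentile of the array was used. Control spots and outlier spots were left out, spots of 1 probe were averaged, and a probe was kept when well above background on every array of at least 1 of the 6 groups, which left 25171 probes. For each gene the probe of highest mean was used, giving 17696 genes, while 11090 genes had no probe past the filter. limma 3.58.1 in R 4.3.3 fitted a mean per group over all 16 arrays, with empirical Bayes moderation (residual degrees of freedom 10, prior degrees of freedom 1.99) and Benjamini-Hochberg adjustment over all genes at 0.05. Sharing the spread over groups was chosen since a group has 2 or 3 arrays. Contrasts were 2C9.G2 minus IgG in each medium and averaged over media, an F test of the difference of that effect between media, and media against each other with IgG and 2C9.G2 weighted equally. Tables were read with the data.table package (version 1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

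There were 31 gene lists, and the 30 with at least 5 genes kept were tested with limma camera at a preset correlation of 0.01, adjusted over lists, with the correlation also estimated. They were integrin subunits, integrin adhesion signalling, beta3 integrin ligands and matrix, study genes, SRCAP, TIP60 and MLL complexes, HSC-associated genes, sort gate genes, Hox and cofactors, STAT5 targets, ERK immediate early genes, megakaryocyte and platelet, erythroid, neutrophil and monocyte, mast cell, basophil and eosinophil, lymphoid, MHC class II and dendritic, stroma and endothelium, cell cycle G1/S, cell cycle G2/M, CDK inhibitors and quiescence, p53 targets, sterol synthesis, interferon response, NF-kB targets, TGF-beta and BMP targets, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, unfolded protein and amino acid response, and heat shock. Within a list, adjustment over the list alone used the p-values of its kept members.

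The contrasts, tests, lists, alternatives and rule for naming genes were fixed before the data were examined. The rule named, for an antibody contrast, the 10 genes of largest log2 fold change each way among those passing (with symbols that are not clone names, and well above background on at least 1 array of both groups), filled up to 5 by smallest p among genes with a log2 fold change of at least 1 and no overlap between groups. For media it named 8 each way, filled up to 3. It also named up to 3 genes each way that were well above background in 1 group only, given as the lowest fold that the background level allows, 6 genes of the F test, up to 4 members of each passing list, and Itgb3, Itgav, Itga2b, Vps72, Mll1 and Runx1. Not every gene so picked is described.

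The alternatives were quantile normalization, normexp background correction with an offset of 50, no filter, a filter of 8 arrays well above background, the deposited value table, slide as a random or fixed block, replicate number as a block, only the arrays of the groups compared, moderation with trend and robust options, array weights, every probe tested, IgG groups only, an estimated correlation for lists, and leaving out each array in turn. Exchanged SCF+TPO antibody labels, the value table matched to the scanner files, slide as a block for lists and for IgG groups only, and lists in IgG groups only were added once the values had been seen. The pipeline was tested on simulated data of the same 17696 genes and groups. For log2 changes of 1, 2 and 4 it recovered 0, 34.3 and 62.1% of changed genes for 2C9.G2 in TPO, 0, 35.8 and 65.2% in SCF, 10.4, 37.3 and 74.2% in SCF+TPO, 23.9, 73.1 and 97% averaged over media, 0, 6 and 50% for the F test, 10.4, 55.2 and 86.4% for TPO against SCF, 20.9, 56.7 and 78.8% for SCF+TPO against SCF and 14.9, 59.7 and 86.4% for SCF+TPO against TPO. False calls were 3 of 67, 4 of 71, 11 of 92, 7 of 136, 3 of 40, 10 of 111, 12 of 116 and 10 of 117 calls in the same order.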

Results

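The series asked how 2C9.G2, an antibody against integrin beta 3, alters gene expression in cultured hematopoietic stem cells, and how that depends on the cytokine. Mouse CD34-KSL stem cells grew with 2C9.G2 or a control IgG in stem cell factor (SCF), thrombopoietin (TPO) or both (SCF+TPO), and CD48-KSL cells were then sorted for 1-colour arrays. There were 16 arrays in 6 groups: SCF with IgG (n = 3) and with 2C9.G2 (n = 2), TPO with IgG (n = 2) and with 2C9.G2 (n = 3), and SCF+TPO with IgG (n = 3) and with 2C9.G2 (n = 3). Of the genes on the array, 17696 were tested. The labels do not say whether the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these arrays, whose number limits precision.

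Integrin beta 3 itself (Itgb3), the target of the antibody and partner of the alpha chains Itgav and Itga2b, was well above background on all 16 arrays, with group means of its probe from 7.50 to 7.90 log2 units above the 75th percentile of the array. 2C9.G2 minus IgG was 0.16 ± 0.263 (SE) in SCF, -0.13 ± 0.263 in TPO and -0.26 ± 0.235 in SCF+TPO for Itgb3 (adjusted p = 0.957, 0.876 and 1), with 2 of 2, 2 of 3 and 3 of 3 antibody arrays on that side of the IgG mean. A second Itgb3 probe gave 0.47, 0.23 and -0.07. Itgav differed by 0.52, -0.35 and 0.00 and Itga2b by 0.26, -0.48 and 0.03, and neither passed in any medium. These values and all later ones in SCF+TPO take the antibody from the scanner files. In the deposited value table the SCF+TPO columns matched the scanner files of the other antibody, so every sign of an antibody effect in SCF+TPO turns if the table is right. The probe for Itgb3 lies on chromosome 11 from 104776217 to 104776287 in mouse build mm7, which all positions below use. The annotation gave no exons in that build, so the part of a gene that a probe covers is not stated.

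**Figure D1:**
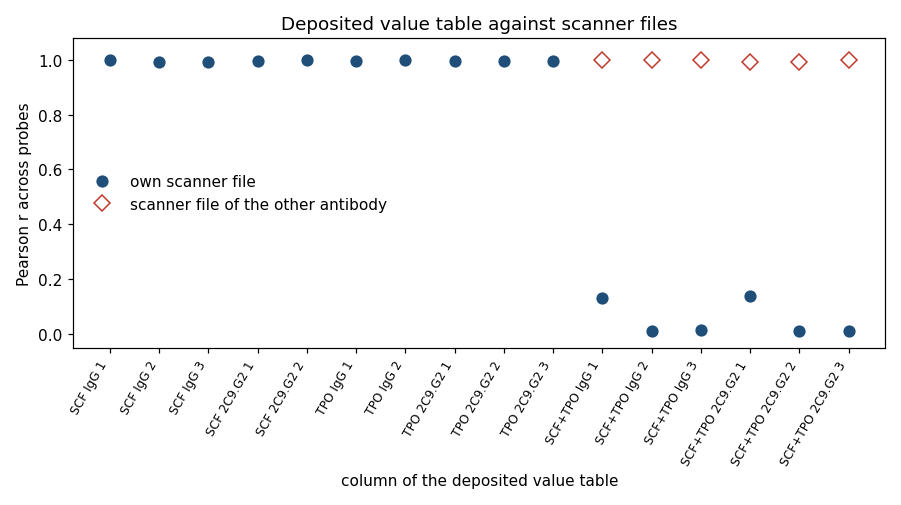
Correlation of each column of the deposited value table with its own scanner file and, for the 6 SCF+TPO columns, with the scanner file of the other antibody that matched it.

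In TPO, a small set of genes differed between 2C9.G2 and IgG. Pdpr, which encodes the regulatory subunit of pyruvate dehydrogenase phosphatase, was 17.7-fold higher with 2C9.G2 (log2 fold change 4.15 ± 0.34 SE, n = 3 and 2 arrays, adjusted p = 0.000635), with means of -2.88 in IgG and 1.27. The difference lay in the 2 TPO IgG arrays (-2.78 and -2.98), as Pdpr means in SCF and SCF+TPO ran from 0.10 to 1.44. Rab4b, a GTPase of recycling endosomes, rose by 4.35 ± 0.827 (adjusted p = 0.0464). Npm2, a histone chaperone best known from oocytes, fell by 4.14 ± 0.662 (adjusted p = 0.0289), and Dhx8, an RNA helicase of the spliceosome, fell by 2.07 ± 0.259 (adjusted p = 0.0112). St6galnac2, a sialyltransferase, fell by 2.52 ± 0.464 (adjusted p = 0.0447), and Ankrd41, an ankyrin repeat gene, by 3.0 ± 0.487 (adjusted p = 0.0317). Rab4b and Mc5r below were well above background on 1 of 2 IgG arrays, and Npm2 and Ankrd41 on 1 of 3 antibody arrays, so the sizes of these folds rest on signal near background. As with Pdpr, the TPO IgG mean stood apart from every other group for Npm2 (-0.26 against -4.40 to -2.21) and Mc5r (-3.54 against -1.805 to -0.57). Dhx8, by contrast, was lowest in TPO with 2C9.G2 (-2.915 against -2.27 to -0.34 in other groups).

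In all, 94 genes passed an adjusted p of 0.05 in TPO, 13 higher and 81 lower with 2C9.G2 (7 and 27 under quantile normalization, 2 and 12 with normexp), and 2464 had an unadjusted p under 0.05. The calls leaned on the spread of other groups and on single arrays: with only the TPO arrays 0 genes passed in limma (1526 unadjusted), with array weights 12, and without TPO IgG 1 14. The other passing genes picked by size were Raph1 (3.35), a lamellipodin gene of the actin cytoskeleton, Mc5r (2.97), a melanocortin receptor gene, Pus7 (2.85), a pseudouridine synthase gene, Rnf103 (2.82), a ubiquitin ligase gene, Hmmr (2.65), a hyaluronan receptor gene of the mitotic spindle, and Layn (2.49), a lectin gene. On the lower side were Slc23a2 (-2.67), a vitamin C transporter gene, Moxd2 (-2.47), Pira1 (-2.07), Sdk2 (-2.06), a cell adhesion gene, Dhx34 (-2.03), a helicase gene, and A26c3 (-2.0), and their adjusted p ran from 0.0152 to 0.0493 across both sides. For all 18 genes named, every 2C9.G2 array lay beyond every IgG array of TPO. Other probes of the same gene gave 3.07 for Pus7 and -0.21 for St6galnac2, but went the other way for Rnf103 (-0.58), Dhx8 (0.14) and, at 1 of 2 probes, Dhx34 (-0.44 to 0.09). A further 552 genes were well above background in IgG and on no 2C9.G2 array, of which 29 passed, and 46 showed the opposite, of which 2 passed. The largest bounds, Wdr78 at least 16.6-fold higher (adjusted p = 0.202) and Gne, a sialic acid synthesis gene, at least 10.5-fold lower (adjusted p = 0.0701), did not pass. The positions are chromosome 8, 109735038 to 109735097 for Pdpr, chromosome 7, 24091813 to 24093334 for Rab4b, chromosome 14, 65291932 to 65291991 for Npm2, chromosome 11, 101855035 to 101855094 for Dhx8, chromosome 11, 116785771 to 116785825 for St6galnac2 and chromosome 8, 69875600 to 69875659 for Ankrd41.

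Vps72, Mll1 and Runx1 are genes that the published study of these cells is remembered to have singled out, so they are not independent evidence. Vps72, a subunit of the SRCAP and TIP60 chromatin complexes, was 1.39 higher with 2C9.G2 in TPO (SE 0.515, 95% interval 0.27 to 2.52, adjusted p = 0.247), with 3 of 3 antibody arrays above both IgG arrays, but did not pass. As with Pdpr, the difference lay in the TPO IgG arrays. Their Vps72 mean of -0.62 was below that of every other group (0.53 to 1.35). Runx1, a transcription factor of stem cell emergence, differed by 1.29 ± 0.651 (adjusted p = 0.413), while a second Runx1 probe gave -0.29, and Mll1, a histone methyltransferase, by 0.60 ± 0.666 (adjusted p = 0.755). In SCF the values were -0.44 for Vps72, -0.90 for Runx1 (second probe 1.21) and -0.59 for Mll1, and in SCF+TPO 0.61, 0.53 and 0.91. As a list, these study genes (3 of 3 kept, too few for a list test) had a median of 1.29 in TPO, -0.59 in SCF and 0.61 in SCF+TPO. The Vps72 probe lies on chromosome 3 from 94992297 to 94992627.

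**Figure D2:**
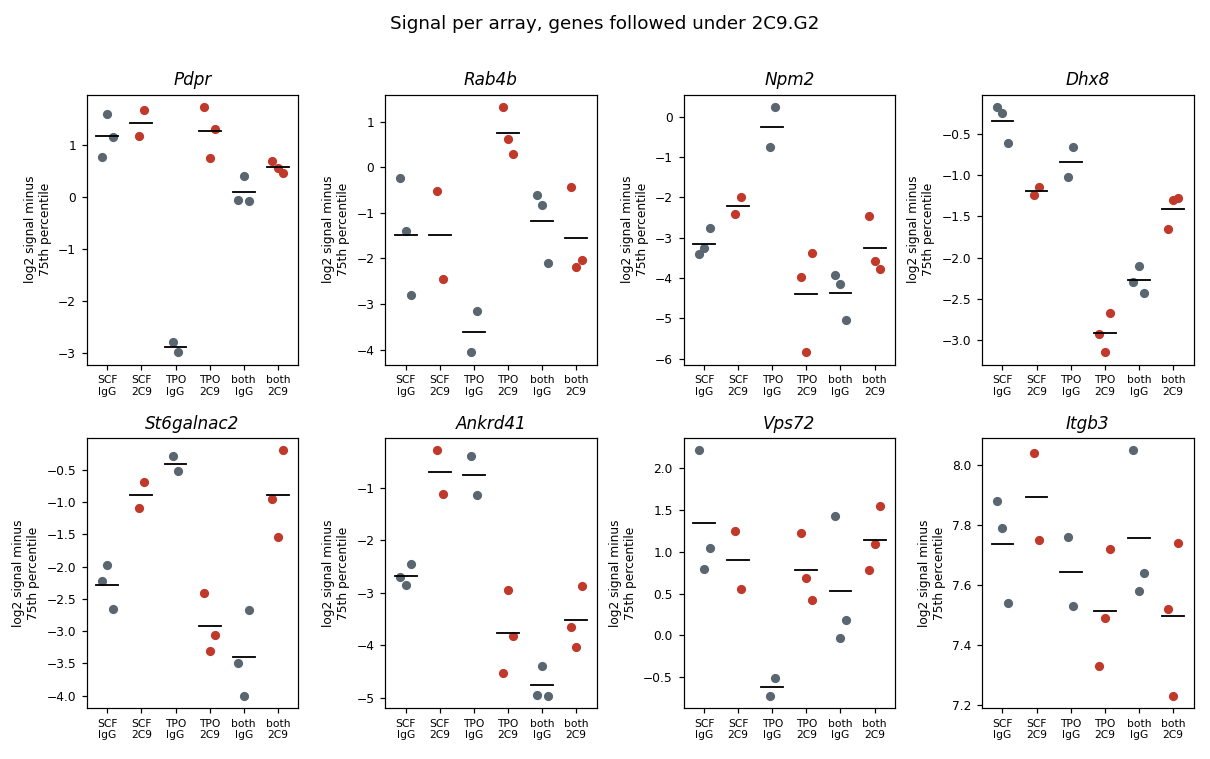
Log2 signal of 8 genes on each array, relative to the 75th percentile of the array, with IgG in grey, 2C9.G2 in red and bars at group means. Antibody labels of SCF+TPO follow the scanner files and are exchanged in the deposited value table.

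Among the fixed gene lists in TPO, hypoxia and glycolysis genes (33 kept) were higher with 2C9.G2, with a median of 0.31, or 0.47 relative to all genes. None of its members passed over all genes or adjusted over the list alone, and the members with the smallest p were Pdk1 (1.77) and Pdk3 (0.73), kinases that restrain pyruvate dehydrogenase, and the glycolytic enzymes Aldoa (0.81) and Tpi1 (0.79). The camera test gave adjusted p = 0.00935, and adjusted p = 0.462 with an estimated correlation. Cytosolic ribosomal protein genes (75 kept, median 0.12, 0.27 relative to all genes, adjusted p = 0.0207) and oxidative phosphorylation genes (65 kept, median 0.13, 0.28 relative, adjusted p = 0.0336) had 0 and 1 members passing adjusted over the list alone, the latter lower. Both lists had adjusted p = 0.705 with an estimated correlation. None of these 3 lists passed under quantile normalization (adjusted p = 0.084, 0.954 and 0.728) or under normexp background correction (0.591, 0.958 and 0.936), where the ribosomal protein list turned to lower. Without TPO IgG 1 none of the 3 passed (adjusted p = 0.28 for each), nor without TPO 2C9.G2 3 (0.0519, 0.103 and 0.0614), and the oxidative phosphorylation list failed also without TPO 2C9.G2 1 (0.0776) or 2 (0.056). The median of all genes was -0.15 in TPO and 0.05 with normexp, a move that by itself shifts every value relative to it. In the main fit the brightest of 5 brightness classes had a median of 0.06. These 3 lists were not set against genes of like brightness. TPO with 2C9.G2 had a slide to itself, so that antibody and slide cannot be told apart in TPO.

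In SCF, a single transcript passed, and no named gene did. The passing transcript, ENSMUST00000056619, was higher with 2C9.G2 (adjusted p = 0.0421, n = 2 and 3 arrays). It was well above background on 2 arrays in all, those of SCF with 2C9.G2, and on no SCF IgG array, so no size is given. It was named after its values were seen. With limma, 1791 genes had an unadjusted p under 0.05. The named genes with the smallest p, none of them passing, were Tmcc3 (3.21 ± 0.615, adjusted p = 0.142), an endoplasmic reticulum membrane gene, and Egflam (3.44 ± 0.721, adjusted p = 0.149), a matrix gene, on the higher side, with Ercc6l (1.80), Atg3 (1.35) and Ankrd41 (1.97) next. On the lower side stood Col11a1 (-1.55 ± 0.246, adjusted p = 0.101), a fibrillar collagen gene, Hcn4 (-1.43) and Scn4a (-1.21), ion channel genes, Gja3 (-1.47), a connexin gene, and St6gal2 (-1.32). For each gene on the lower side, the SCF IgG mean was the highest of the 6 groups. It was -1.49 for Col11a1 against -3.39 to -2.27 in other groups, and 0.52 for Hcn4 against -0.97 to -0.36. These differences thus lay in the SCF IgG arrays. Detection itself was uneven: 1098 genes were well above background in IgG but on no 2C9.G2 array (0 passing), against 51 the other way (1 passing).

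Lymphoid genes (18 kept) were lower with 2C9.G2 in SCF, with a median of -0.86, or -0.78 relative to all genes. Over all genes 0 passed, and adjusted over the list alone 4 fell: Cd19 (-1.42 ± 0.28), a B cell coreceptor gene, Vpreb3 (-0.89 ± 0.29, with a second probe at 0.11), a surrogate light chain gene, and Pax5 and Igll1, which were well above background on neither 2C9.G2 array, so that no size is given for them. Igll1 was well above background in SCF with IgG only, so it passed the filter through the group where it was high, and its fall is no independent support. Camera gave adjusted p = 0.021, with adjusted p = 0.193 with an estimated correlation and 0.437 with normexp. The list did not pass without SCF IgG 2 (adjusted p = 0.0796), SCF 2C9.G2 1 (0.0631) or SCF 2C9.G2 2 (0.0822). Dim genes in general were lower here (median -0.56 in the dimmest of 5 brightness classes), so the list was not shown to stand apart from them. The SCF groups were on separate slides, so antibody and slide cannot be told apart here either, and with normexp no list passed.

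In SCF+TPO, a single transcript, AK028771, passed and was higher with 2C9.G2 (adjusted p = 0.0162, n = 3 and 3 arrays), named after its values were seen. It was well above background on 5 arrays, among them every SCF+TPO 2C9.G2 array but no SCF+TPO IgG array, so no size is given. With limma 741 genes had an unadjusted p under 0.05. This is less than the share of 0.05 of the 17696 genes tested that would be expected without any effect. No named gene passed. Those with the smallest p were Neo1 (-2.56 ± 0.401, adjusted p = 0.125), a netrin receptor gene used as a stem cell marker, and St6galnac2 (2.50 ± 0.415, adjusted p = 0.18, second probe -0.20). After them came Serpinh1 (2.92), a collagen chaperone gene, Sbk1 (1.92), Hfm1 (1.01, on 1 of 3 IgG arrays well above background), Fath (1.00), Slc40a1 (-3.71, well above background on 1 of 3 antibody arrays, so of uncertain size), the iron exporter gene, P2rx1 (-2.27), a platelet ATP receptor gene, Cerk (-1.80) and Tent2 (-1.31). These are the only groups of 1 medium that shared a slide. Within the shared slide, which held 1 of the 2C9.G2 arrays and all 3 IgG arrays, the differences were -3.0 for Neo1, 2.44 for St6galnac2, 3.1 for Serpinh1, 2.58 for Sbk1, -2.12 for P2rx1, -1.78 for Slc40a1, -1.97 for Cerk, 0.81 for Hfm1, 1.2 for Fath and -1.83 for Tent2. With slide as a fixed block, which sets the same 1 array against the 3 IgG arrays, 0 genes passed in limma and 963 had an unadjusted p under 0.05.

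Interferon response genes (37 kept) were lower with 2C9.G2 in SCF+TPO, with a median of -0.40, and 31 of 37 lay below 0. Stat2 and Irf7 (-1.64), which carry and amplify the interferon signal, Parp14 (-1.73) and Ifitm3 (-0.35), which blocks viral entry, had the smallest p, with Stat2 well above background on no 2C9.G2 array, and 0 members passed over all genes or adjusted over the list alone. Camera gave adjusted p = 0.001, and adjusted p = 0.255 with an estimated correlation. The call depended on 1 array, as the list did not pass without SCF+TPO 2C9.G2 1 (adjusted p = 0.0639). Slide as a block leaves that array alone against the 3 IgG arrays (median -0.62), so it is no further support. Unfolded protein and amino acid response genes (37 kept, median -0.32, adjusted p = 0.0234) included Slc7a11 (-2.66, well above background on 1 of 3 antibody arrays), Slc3a2 (-0.95), Pdia6 (-0.68) and Hyou1 (-0.48), with 0 passing either way and adjusted p = 0.71 with an estimated correlation. Ribosomal protein genes (75 kept, median -0.10, 0 passing either way, adjusted p = 0.0234) had adjusted p = 0.875 with an estimated correlation. With the same block neither passed (adjusted p = 0.515 and 0.626). The unfolded protein list did not pass without SCF+TPO IgG 2 (0.0895), IgG 3 (0.352) or any SCF+TPO 2C9.G2 array (0.0639 to 0.0899), nor the ribosomal list without IgG 2 (0.957), 2C9.G2 1 (0.0757) or 2C9.G2 2 (0.529). All 3 list directions turn with the antibody labels.

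Averaged over the 3 media, 5 genes passed. Pdpr was 1.63 ± 0.19 higher (adjusted p = 0.011), an average that came mostly from TPO (0.25 in SCF, 4.15 in TPO and 0.48 in SCF+TPO). The average of BG067131 below did so too (-0.58, -2.625 and -0.12). By the F test the antibody effect on each of them differed between media (adjusted p = 0.0173 and 0.0203). Tmem17, a ciliary membrane gene, was -3.53 ± 0.354 (adjusted p = 0.00659, well above background on 7 arrays), Olfr1471, an olfactory receptor gene, -1.30 ± 0.161 (adjusted p = 0.0147, well above background on 2 of 8 antibody arrays, so of uncertain size), BG067131 -1.11 ± 0.126 (adjusted p = 0.011) and Col11a1 -0.97 ± 0.137 (adjusted p = 0.0473). Next on the lower side, without passing, was Pdx1 (-1.19 ± 0.208, adjusted p = 0.108, with the same limit on 2 of 8), a pancreatic transcription factor gene. Dim genes in general were lower on this average, with medians from -0.34 in the dimmest of 5 brightness classes to 0.02 in the brightest. The falls of single genes were not set against that. With the SCF+TPO labels exchanged, as in the deposited value table, 168 genes passed (9 higher and 159 lower), among them 4 of the 5. The direction split was 1 higher and 4 lower, and 1 and 2 under quantile normalization, while 0 passed in limma with normexp (1332 unadjusted) or without SCF 2C9.G2 1 (1866). Genes of the SRCAP, TIP60 and MLL complexes (24 kept, median 0.13, camera adjusted p = 0.0388, and adjusted p = 0.224 with an estimated correlation) passed as a list, with Actr6 (0.93), Mbtd1 (0.68), Vps72 (0.52) and Hcfc1 (0.34) of the smallest p and 0 passing either way. For Actr6, Mbtd1 and Vps72, though not for Hcfc1, the TPO IgG mean was the lowest of the 6 groups (-1.45, 0.69 and -0.62). Oxidative phosphorylation genes also passed (65 kept, median 0.05, adjusted p = 0.0388, and adjusted p = 0.656 with an estimated correlation), again with 0 members passing. The SRCAP, TIP60 and MLL list kept its call in 5 of 22 alternatives and lost it with the SCF+TPO labels exchanged (adjusted p = 0.132), and the oxidative phosphorylation list kept its call in 7 of 22. On leaving out 1 array both passed without SCF IgG 1, SCF 2C9.G2 2, SCF+TPO IgG 2 or SCF+TPO 2C9.G2 1, and the second also without TPO IgG 2, while without any other array they did not (adjusted p from 0.0557 to 0.102 and from 0.0597 to 0.251).

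The antibody effect differed between media for 10 genes by the F test, and 1877 had an unadjusted p under 0.05. In limma 0 passed with normexp (1450 unadjusted), with the replicate block (1797) or without TPO IgG 1 (1696). Pdpr (0.25 in SCF, 4.15 in TPO, 0.48 in SCF+TPO) had adjusted p = 0.0173 and stood apart in TPO in both pairwise tests (adjusted p = 0.0197 against SCF and 0.00926 against SCF+TPO). Its TPO IgG mean (-2.88) lay below that of every other group (0.10 to 1.44). Dhx8 (-0.85, -2.07 and 0.86, adjusted p = 0.0203), St6galnac2 (1.39, -2.52 and 2.50, adjusted p = 0.0237) and Ankrd41 (1.97 in SCF, -3.0 in TPO, and no size in SCF+TPO, as no IgG array there was well above background, adjusted p = 0.0317) passed as labelled. With the SCF+TPO labels exchanged Pdpr passed (adjusted p = 0.00705), and these 3 did not (0.455, 0.116 and 0.108). The second St6galnac2 probe, with nearly the same value in TPO and SCF+TPO, did not show the difference, and the other Dhx8 probe did not fall in TPO. Phka1, a phosphorylase kinase gene, and Klk11, a kallikrein gene, came next without passing (adjusted p = 0.0503 and 0.0978). Between pairs of media, 4 genes passed for TPO against SCF (1 higher, 3 lower), 12 for SCF+TPO against TPO (10 and 2) and 0 for SCF+TPO against SCF, where limma gave 1521 at an unadjusted p under 0.05. Vps72, Runx1 and Mll1 were not among the passing genes.

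Across all genes, the estimated antibody effects in different media, each with its own IgG arrays, were only weakly correlated. Noise in estimates from so few arrays lowers r even where effects agree. A low r therefore does not show that the effects themselves were unrelated. Pearson r was 0.075 between SCF and TPO, where 1 of 100 relabelings within media was as large (highest other 0.061, Spearman 0.133). It was -0.014 between SCF and SCF+TPO (34 of 100 as large) and -0.035 between TPO and SCF+TPO (7 of 100 as large). Dim genes were lower with the antibody in both SCF and TPO, as described next. How much of the r of 0.075 came from that was not tested.

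Dim genes gave less signal with 2C9.G2 in SCF and TPO. With genes in 5 classes by brightness, the median log2 fold change ran from -0.56 in the dimmest class to 0.04 in the brightest in SCF, from -0.43 to 0.06 in TPO, and from -0.01 to -0.04 in SCF+TPO. In the dimmest class, quantile normalization gave -0.39 in SCF and -0.20 in TPO, and normexp turned both (0.02 and 0.18), while in SCF+TPO they gave 0.12 and -0.15. The share of probes well above background was 62.3 ± 0.7% (SD) in SCF with IgG and 54.7 ± 2.3% with 2C9.G2, 58 ± 0.5% and 52.4 ± 0.8% in TPO, and 57.8 ± 2.5% and 57.5 ± 2% in SCF+TPO. The filter kept genes well above background in 1 group alone, which favours falls from a group of high detection such as SCF with IgG. How much of the lower dim signal came from that was not tested.

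**Figure D3:**
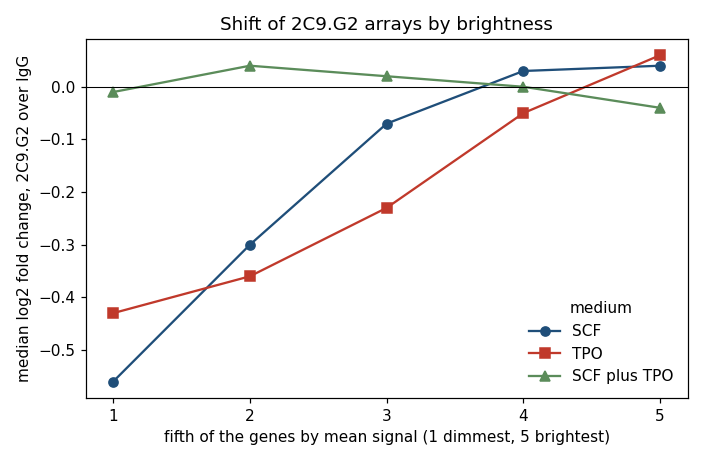
Median log2 fold change (2C9.G2 minus IgG) by brightness class in each medium, with the antibody of SCF+TPO as in the scanner files, where the sign turns if the deposited value table is right. In SCF and TPO the fall in the dimmest class turns to a small rise with normexp background correction.

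Between TPO and SCF (n = 5 and 5 arrays, antibody and IgG weighted equally), Socs2, a feedback inhibitor of JAK-STAT signalling, was 9.08 ± 0.401 log2 units higher in TPO (adjusted p = 5.9e-07), and a second probe gave 3.09. Ncam2, a neural adhesion gene, rose by 9.75 ± 1.09 (adjusted p = 0.000668, second probe 4.54), Id1, an inhibitor of helix-loop-helix factors, by 5.10 ± 0.677 (adjusted p = 0.00239, second probe 5.03), and Pim1, a STAT5-induced kinase, by 4.75 ± 0.756 (adjusted p = 0.00791, second probe 3.69). Lower in TPO were Gem (-7.61 ± 0.562, adjusted p = 2.7e-05), a GTPase induced by mitogens, Bcl6 (-4.99 ± 0.944, adjusted p = 0.0249), a repressor that STAT5 restrains, Dusp6 (-4.76 ± 0.751, adjusted p = 0.00782), a phosphatase that switches off ERK, and Thbd (-4.09 ± 0.448, adjusted p = 0.000599), the thrombomodulin gene. Socs2 and Ncam2 were well above background on 1 of 5 SCF arrays, Id1 on 2 and Pim1 on 3, and Gem and Bcl6 on 2 of 5 TPO arrays, so the sizes of these folds rest on signal near background. On every TPO array each of these 8 genes lay on the same side of the SCF mean.

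In all 241 genes passed, 123 higher and 118 lower in TPO (120 and 76 with normexp, 124 and 81 with quantile normalization), and 2945 had an unadjusted p under 0.05. Without TPO IgG 2 the count was 123. The median of all genes was -0.14. Other passing genes picked by size were Enah (7.38), an actin regulator gene, Stxbp6 (6.03), Insyn1 (5.12) and Tspan7 (4.81) on the higher side, and Pcdh7 (-5.71), a protocadherin gene, Ddx4 (-5.50), a germ cell helicase gene, Etv5 (-4.12), an ERK-induced factor gene, and Pdp1 (-3.62) on the lower. Of these Stxbp6 was well above background on 1 of 5 SCF arrays, Enah and Insyn1 on 2, and Pcdh7, Ddx4 and Etv5 on 1 of 5 TPO arrays, so their sizes and rank are uncertain. Genes on no SCF array well above background numbered 10, all passing, with Ccn3, a matricellular gene of stem cells, at least 47.2-fold higher in TPO (adjusted p = 2.47e-06), Clec10a, a lectin gene, at least 20.1-fold and Arid5a at least 5.44-fold. Of 13 such genes on no TPO array, 5 passed, with Zkscan4 at least 12.6-fold lower (adjusted p = 0.000263). Itga2b differed by -1.70 and Vps72 by -1.05 (adjusted p = 0.321 and 0.175), and Itgb3 by -0.24. The positions are chromosome 10, 94973417 to 94973476 for Socs2, chromosome 16, 81593145 to 81593204 for Ncam2, chromosome 2, 152478167 to 152478226 for Id1, chromosome 17, 27685743 to 27685802 for Pim1, chromosome 4, 11641396 to 11641455 for Gem, chromosome 16, 23623679 to 23623738 for Bcl6, chromosome 10, 98828759 to 98828818 for Dusp6 and chromosome 2, 148145356 to 148145415 for Thbd. SCF and TPO arrays were on different slides, so that medium and slide cannot be told apart between them.

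**Figure D4:**
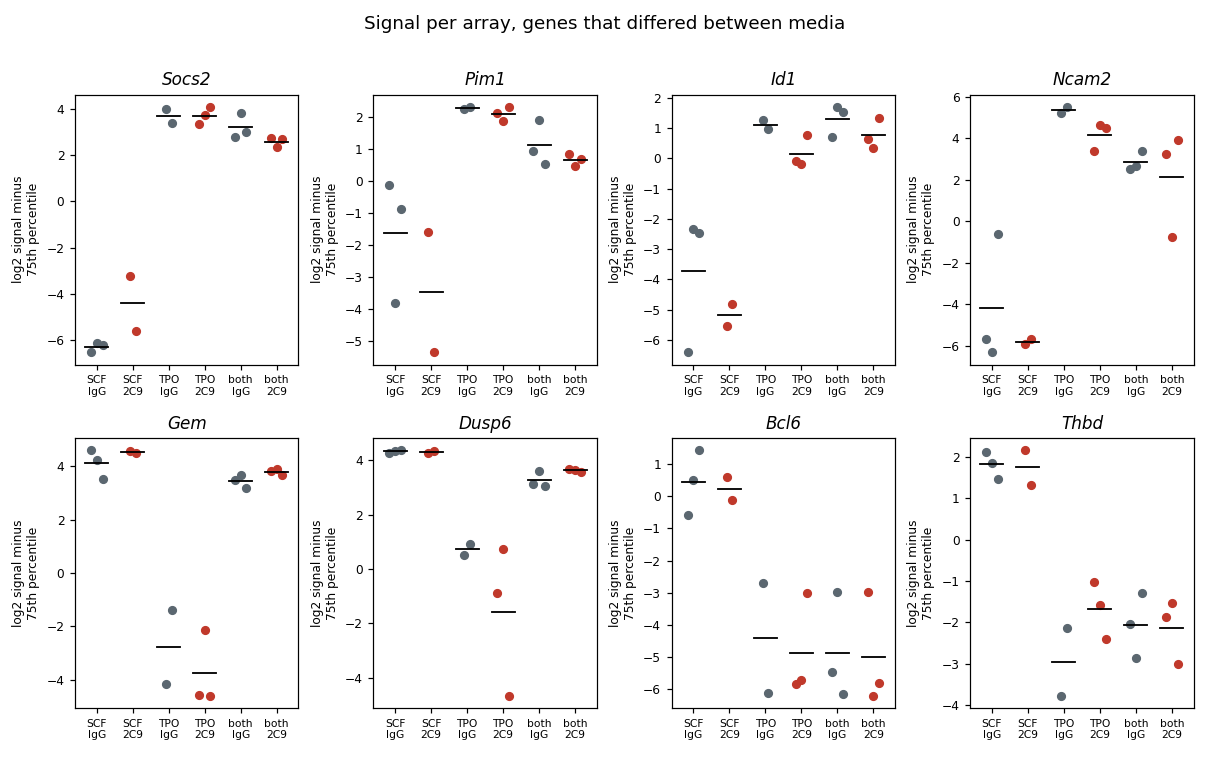
Log2 signal of 8 genes on each array, relative to the 75th percentile of the array, with IgG in grey, 2C9.G2 in red and bars at group means. The antibody labels of SCF+TPO follow the scanner files.

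Of the gene lists, 10 passed between TPO and SCF. NF-kB targets (19 kept) were higher in TPO, with a median of 1.13 (1.27 relative to all genes, adjusted p = 1.1e-07). Over all genes 3 of them rose, namely Ltb (2.48 ± 0.322), a lymphotoxin gene, Ier3 (2.61 ± 0.413), a stress response gene, and Nfkbiz (2.28 ± 0.446), an NF-kB cofactor gene, and 8 rose adjusted over the list alone. STAT5 targets (18 kept, median 0.48, adjusted p = 0.000365) had 4 higher and 2 lower over all genes, and 7 and 2 over the list alone, with Socs2, Pim1 and Pim2 (3.46 ± 0.333) higher and Ccnd1 (-1.51 ± 0.18), a cyclin gene, and Bcl6 lower. Interferon response genes (37 kept, median 0.32, adjusted p = 5.93e-05) had Ifitm3 (1.47 ± 0.152) and Oas2 (2.77 ± 0.39), an antiviral enzyme gene, higher, 2 over all genes and 2 over the list alone. Hypoxia and glycolysis genes (33 kept, median 0.46, adjusted p = 2.49e-06) had 2 higher and 1 lower over all genes (4 and 1 over the list alone), with Pdk3 (1.06) and Mif (1.2), a cytokine gene, higher and Ndrg1 (-2.0) lower. Unfolded protein and amino acid response genes (37 kept, median 0.23, adjusted p = 5.01e-05) had 1 higher over all genes, Xbp1 (2.17 ± 0.241), the factor of the secretory stress response, and 2 over the list alone.

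Lower in TPO were megakaryocyte and platelet genes (31 kept, median -0.76, adjusted p = 0.000211), although TPO is the cytokine of megakaryocytes. Cavin2 (-2.81 ± 0.405), a caveola gene of platelets, and Rgs18 (-1.52 ± 0.279), a brake on platelet receptors, fell over all genes while Vwf (1.99 ± 0.242), which marks platelet-biased stem cells, rose, and adjusted over the list alone 14 fell and 1 rose. Mitosis genes (cell cycle G2/M, 40 kept, median -0.41, adjusted p = 0.00502) had 0 passing either way, with Aurkb (-1.25), Mki67 (-0.72) and Cdca8 (-0.66) of the smallest p. Each of these 7 lists also passed with an estimated correlation (adjusted p from 0.0334 to 0.041), although STAT5 targets did not in the deposited value table (adjusted p = 0.477). The other 3 passed with the preset correlation only. Integrin subunits (14 kept) were all below 0, with a median of -0.51, Itgb2 (-1.54), the leukocyte beta chain gene, Itga8 (-1.45, well above background on 1 of 5 TPO arrays, so of uncertain size) and Itga7 (-0.48) of the smallest p, 0 passing either way and adjusted p = 0.0159, and adjusted p = 0.276 with an estimated correlation. That list did not pass without TPO 2C9.G2 1 (0.073), in IgG groups only (0.119) or in the deposited value table (0.0518), and dim genes in general were lower in TPO than in SCF (median -0.41 in the dimmest of 5 classes), so it was not shown to stand apart from them. Ribosome biogenesis and MYC targets (41 kept, median 0.21, adjusted p = 0.000748) had adjusted p = 0.101 with an estimated correlation. Oxidative phosphorylation genes (65 kept, median 0.14, adjusted p = 0.000971) had adjusted p = 0.306 with an estimated correlation, and neither list had a passing member.

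**Figure D5:**
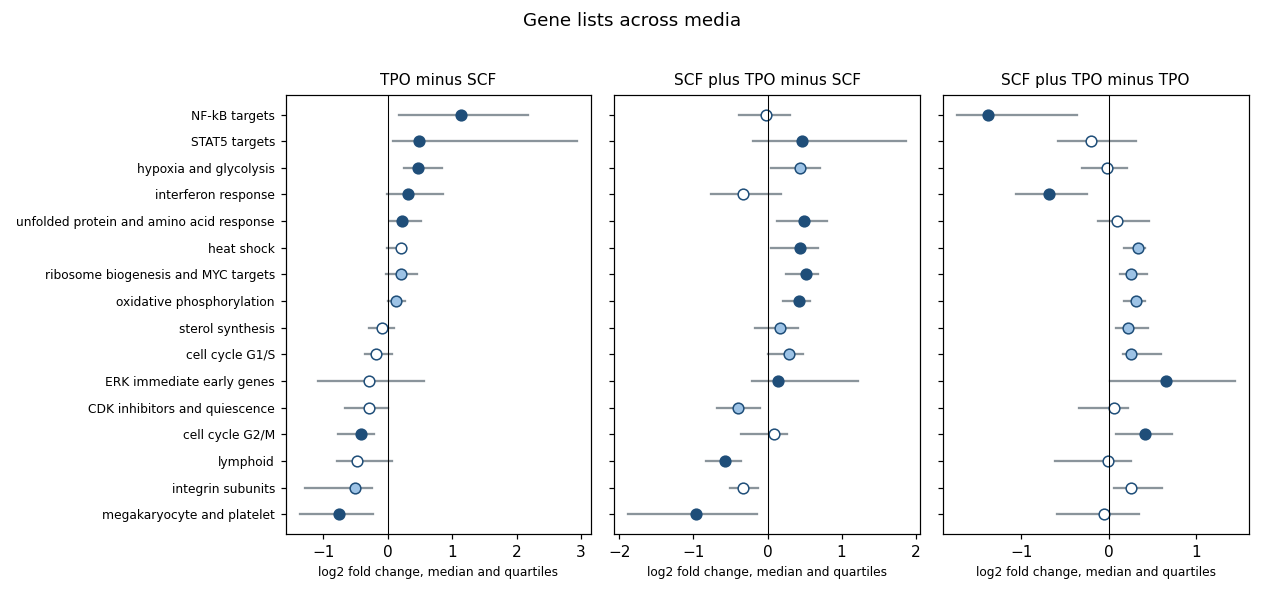
Median log2 fold change (points) and quartiles (lines) of 16 gene lists in the 3 comparisons of media. Filled dark points passed with the preset and with an estimated correlation between genes, light points with the preset only, and open points with neither.

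Socs2, Ncam2, Enah and Id1 were higher in SCF+TPO than in SCF as well. With both cytokines (n = 6 against 5 arrays in SCF), Socs2 rose by 8.26 ± 0.381 (adjusted p = 9.65e-07, second probe 2.14), Ncam2 by 7.47 ± 1.037 (adjusted p = 0.00369), Enah by 6.60 ± 0.567 (adjusted p = 0.000105), and Id1 by 5.50 ± 0.642 (adjusted p = 0.00106). Egr1, an immediate early factor of the ERK pathway, rose by 5.02 ± 0.957 (adjusted p = 0.0223). Bcl6 (-5.29 ± 0.895, adjusted p = 0.0122), Pcdh7 (-5.26 ± 0.617, adjusted p = 0.00108), Thbd (-3.88 ± 0.425, adjusted p = 0.000711) and Plek (-3.78 ± 0.567, adjusted p = 0.00615), a kinase substrate gene of platelets, fell. The limit of signal near background holds here too, for Socs2 and Ncam2 (1 of 5 SCF arrays well above it), Enah and Id1 (2 of 5), and Pcdh7 and Bcl6 (1 and 2 of 6 SCF+TPO arrays). All 6 SCF+TPO arrays lay on the same side of the SCF mean for each of these genes.

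In all 437 genes passed, 214 higher and 223 lower (303 and 202 with normexp, 192 and 188 under quantile normalization), and 3555 had an unadjusted p under 0.05. Without SCF 2C9.G2 2 the count was 110, and 9 of 16 runs without 1 array moved it. The median of all genes was -0.10. Further large differences were Insyn1 (4.87), Stxbp6 (4.79) and Tspan7 (4.75) on the higher side, and Zkscan4 (-5.53), Olfr632 (-4.23), an olfactory receptor gene, Dpp4 (-3.90), a peptidase gene that cleaves cytokines, and Dnajc6 (-3.89) on the lower. Stxbp6 was well above background on 1 of 5 SCF arrays and Insyn1 on 2, and Zkscan4, Olfr632 and Dpp4 on 1 of 6 SCF+TPO arrays and Dnajc6 on 2, so these sizes are uncertain. Of 5 genes on no SCF array well above background 4 passed, with Clec10a at least 15.8-fold, Ccn3 at least 7.7-fold and Fos, the immediate early partner of Jun, at least 5.92-fold higher (adjusted p = 4.42e-05). Of 10 the other way 8 passed, with Abcg3 at least 7.09-fold lower (adjusted p = 0.02).

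Oxidative phosphorylation genes (65 kept) were higher in SCF+TPO than in SCF, with a median of 0.43 (0.53 relative to all genes, adjusted p = 5.64e-14). Over all genes 6 rose, among them Ndufs6 (0.93 ± 0.167) and Ndufa8 (0.71 ± 0.148) of complex I, Cyc1 (1.05 ± 0.209) of complex III and Atp5b (0.87 ± 0.163) of the ATP synthase, and 9 rose adjusted over the list alone. Ribosome biogenesis and MYC targets (41 kept, median 0.52, adjusted p = 6.31e-10) had 4 higher over all genes and 10 over the list alone, with Hspd1 (0.76 ± 0.148), the mitochondrial chaperonin, Eif4a1 (0.80 ± 0.174), a translation helicase, Ldha (0.64 ± 0.145) and C1qbp (0.75 ± 0.178). Heat shock genes (19 kept, median 0.44, adjusted p = 3.76e-05) had 2 higher over all genes, Hspd1 and Hspa8 (0.71 ± 0.141), and 6 over the list alone. Unfolded protein and amino acid response genes (37 kept, median 0.50, adjusted p = 5.93e-06) had 2 higher, Xbp1 (1.2 ± 0.229) and Hspa5 (0.67 ± 0.16), a chaperone gene, and 3 over the list alone. ERK immediate early genes (32 kept, median 0.14, adjusted p = 0.00386) had Fos, Egr1 and Jund (1.62 ± 0.166) higher over all genes and 8 over the list alone. STAT5 targets (18 kept, median 0.47, adjusted p = 0.00214) had 4 higher and 2 lower (5 and 2 over the list alone), Socs2 and Id1 being higher and Bcl6 lower.

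Megakaryocyte and platelet genes (31 kept, median -0.97, -0.87 relative to all genes, adjusted p = 3.76e-05) had 7 lower over all genes, among them Cavin2 (-3.35 ± 0.384), Mpl (-1.93 ± 0.228), the TPO receptor gene, Lat (-1.87 ± 0.312) and Plek, and 1 higher, Vwf (1.19 ± 0.229). Adjusted over the list alone 13 fell and 1 rose. Lymphoid genes (18 kept, median -0.57, adjusted p = 0.00591) had 0 passing over all genes and 4 lower over the list alone, but dim genes in general were lower here too (median -0.42 in the dimmest of 5 classes). For Cd19 (-0.68) the difference lay in the SCF IgG arrays (-0.5 to 0.14), as SCF 2C9.G2 arrays (-1.6 and -1.67) were like those of SCF+TPO (-1.75 to -1.47). Each of these 8 lists passed with an estimated correlation (adjusted p from 0.0158 to 0.0378), while STAT5 targets and lymphoid genes did not pass in the deposited value table (adjusted p = 0.501 and 0.0987). Another 4 passed with the preset correlation only. Hypoxia and glycolysis genes (33 kept, median 0.44, adjusted p = 0.000355) had 4 higher and Ndrg1 (-2.81) lower, 9 and 2 over the list alone, and adjusted p = 0.0662 with an estimated correlation. DNA replication genes (cell cycle G1/S, 35 kept, median 0.28, adjusted p = 0.0111, 0 passing either way) had adjusted p = 0.404 with an estimated correlation. Sterol synthesis genes (30 kept, median 0.17, adjusted p = 0.025) had 2 higher over all genes and over the list alone, the fatty acid desaturase genes Scd1 (1.83 ± 0.139) and Scd2 (1.01 ± 0.153), and adjusted p = 0.186 with an estimated correlation. CDK inhibitors and quiescence genes (19 kept, median -0.40, adjusted p = 0.0443) had 1 lower either way, Tsc22d3 (-1.33 ± 0.295), a glucocorticoid-induced gene, and adjusted p = 0.0828 with an estimated correlation. The DNA replication list did not pass without SCF+TPO IgG 2 (0.0535), the sterol list without SCF IgG 1 (0.129), SCF 2C9.G2 1 (0.131) or SCF+TPO 2C9.G2 1 (0.0543), nor the CDK inhibitor list without SCF IgG 1, either SCF 2C9.G2 array, either TPO IgG array, SCF+TPO IgG 2 or 3 or SCF+TPO 2C9.G2 3 (0.0536 to 0.0975). SCF arrays shared no slide with SCF+TPO arrays, so medium and slide cannot be told apart in this comparison.

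Gem, Etv5, Dusp6 and Fos, which mitogens induce, were higher in SCF+TPO than in TPO. With SCF added to TPO (n = 6 against 5 arrays), Gem rose by 6.89 ± 0.533 (adjusted p = 0.000187), Etv5 by 4.78 ± 0.753 (adjusted p = 0.0268), and Dusp6 by 3.89 ± 0.713 (adjusted p = 0.0493), and Fos was at least 5.63-fold higher (adjusted p = 0.000187). Vegfa (-2.16 ± 0.331, adjusted p = 0.0268), the vascular growth factor gene, Ccn3 (-2.61 ± 0.399, adjusted p = 0.0268) and Ltb (-1.95 ± 0.305, adjusted p = 0.0268) fell, as did Sirt4 (-2.30 ± 0.381, adjusted p = 0.0312), a mitochondrial sirtuin gene. In TPO, Gem was well above background on 2 of 5 arrays and Etv5 on 1, so these folds too are uncertain in size. All 6 SCF+TPO arrays were on the same side of the TPO mean for each of them.

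In all 53 genes passed, 24 higher and 29 lower, and 2260 had an unadjusted p under 0.05. Without SCF+TPO 2C9.G2 1 or 2 the count was 12. Other passing genes picked by size were Imp4 (3.47), a ribosome assembly gene, Selp (3.15), the P-selectin gene of platelets, Taco1 (2.74), Fam43a (2.71) and Cfp (2.13), the properdin gene, on the higher side. Serpinh1 (-3.26), Podnl1 (-2.97, well above background on 1 of 6 SCF+TPO arrays), Nsg1 (-2.84) and Igf2bp2 (-2.34), an RNA-binding protein gene, were on the lower. Of 8 genes on no TPO array well above background 3 passed, and 2 of 2 passed the other way, with Dpysl5 at least 20.6-fold lower (adjusted p = 0.0208). TPO with IgG shared a slide with 2 SCF+TPO arrays. With IgG groups only 8 genes passed. With slide as a fixed block as well, where the slide term rests on SCF+TPO 2C9.G2 array 1 against arrays 2 and 3, 0 genes passed in limma and 1218 had an unadjusted p under 0.05. In that fit Gem was 6.18 and Dusp6 2.49, against 6.57 and 2.90 within the shared slide, where the SCF+TPO arrays carried the other antibody label. Vegfa was -0.48 (-1.35 within the slide), Sirt4 -1.11 (-2.28) and Ccn3 -1.70 (-2.04). The Vegfa probe lies on chromosome 17 from 44146842 to 44146901.

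Of the lists, 9 passed between SCF+TPO and TPO. NF-kB targets (19 kept) were lower in SCF+TPO, with a median of -1.39 (adjusted p = 5.84e-09), and had Ltb lower over all genes and 10 lower over the list alone, among them Icam1 (-1.90), an adhesion gene, Cxcl2 (-2.26, well above background on 1 of 6 SCF+TPO arrays), a chemokine gene, and Nfkbiz (-1.68). Interferon response genes (37 kept, median -0.68, adjusted p = 1.76e-09) had 0 lower over all genes and 6 over the list alone, with Ddx58 (-1.56), the RIG-I sensor gene, Ifi27 (-0.94) and Gbp2 (-1.83) of the smallest p. Mitosis genes (40 kept, median 0.41, adjusted p = 7.57e-05) had 0 and 3 higher, namely Cdca8 (0.71), Aurkb (1.35) and Bub1 (1.25). ERK immediate early genes (32 kept, median 0.66, adjusted p = 0.000253) had 4 higher over all genes, Fos, Etv5, Dusp6 and Dusp4 (1.28 ± 0.234), and 7 higher and 2 lower over the list alone. These 4 also passed with an estimated correlation (adjusted p from 0.0124 to 0.0249), but ERK immediate early genes did not in the deposited value table (adjusted p = 0.305). With IgG groups only all 4 passed (adjusted p from 0.000155 to 0.0181). With the slide term above added to that fit, NF-kB targets (median -0.81, adjusted p = 0.0345) and mitosis genes (median 0.63, adjusted p = 0.00124) passed, while interferon response genes (median 0.04, adjusted p = 0.726) and ERK immediate early genes (median 0.22, adjusted p = 0.434) did not. Within the shared slide, where the antibody label differed, the interferon median was -0.58, so whether slide made that difference stays open.

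Another 5 lists passed with the preset correlation only. Oxidative phosphorylation genes (65 kept, median 0.31, adjusted p = 2.15e-07, and adjusted p = 0.117 with an estimated correlation) had 0 higher over all genes and 2 over the list alone, with Atp5b (0.73) and Ndufs1 (0.95), and passed in IgG groups with the slide term (adjusted p = 0.00807). Ribosome biogenesis and MYC targets (41 kept, median 0.25, adjusted p = 0.000794, and adjusted p = 0.118 with an estimated correlation) had 1 higher, Imp4. DNA replication genes (35 kept, median 0.25, adjusted p = 4e-04, and adjusted p = 0.255 with an estimated correlation) had 0 passing either way, with Mcm10 (2.18) and Rrm1 (0.54) of the smallest p. Heat shock genes (19 kept, median 0.34, adjusted p = 0.00362, and adjusted p = 0.0733 with an estimated correlation) had 0 passing either way. Sterol synthesis genes (30 kept, median 0.23, adjusted p = 0.0339, and adjusted p = 0.255 with an estimated correlation) had 0 over all genes and 1 over the list alone. Heat shock genes did not pass without TPO IgG 1 (0.0604), nor did sterol genes without TPO IgG 1 (0.0854), TPO 2C9.G2 1 (0.0602) or 2 (0.0871), SCF+TPO IgG 1 (0.0583) or SCF+TPO 2C9.G2 1 (0.104). None of the last 4 passed in IgG groups with the slide term (adjusted p from 0.13 to 0.457), while all 4 passed in IgG groups without it (0.000643 to 0.013).

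The remaining lists passed in no comparison. HSC-associated genes (51 kept) moved both ways, with 5 higher and 2 lower in TPO than in SCF (median -0.30, adjusted p = 0.958, the test leaning to higher against a negative median and mean), 5 and 5 in SCF+TPO against SCF (median -0.32), and a median of 0.01 with 2C9.G2 in TPO (adjusted p = 0.629, mean -0.15). Sort gate genes (11 kept) had 1 higher and 3 lower in TPO than in SCF (median -0.80, adjusted p = 0.374). Erythroid genes (18 kept) had a median of -0.60 there (adjusted p = 0.162) and -0.50 in SCF+TPO against SCF (adjusted p = 0.0518). Hox and cofactor genes (19 kept) had a median of 0.15 with 2C9.G2 in TPO (adjusted p = 0.59), integrin adhesion signalling genes (38 kept) -0.04 (mean 0.01, adjusted p = 0.616), stroma and endothelium genes (13 kept) -0.54 (adjusted p = 0.281) and TGF-beta and BMP targets (17 kept) -0.69 (adjusted p = 0.302). Beta3 integrin ligands and matrix genes (8 kept) had -0.48 with 2C9.G2 in SCF (adjusted p = 0.436). Neutrophil and monocyte genes (20 kept) had 0.27 in SCF+TPO against SCF (adjusted p = 0.7), and MHC class II and dendritic genes (7 kept) -0.29 (adjusted p = 0.137). Mast cell, basophil and eosinophil genes (13 kept) had a median of -0.19 against a mean of 0.22 between TPO and SCF (adjusted p = 0.676), with 2 higher and 1 lower, and p53 targets (21 kept) a median of 0.09 against a mean of -0.01 (adjusted p = 0.461).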

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

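The tests of the exchanged antibody labels, of the dim signal, apart from quantile normalization, and of loss of transcripts by a ratio were chosen after the results were seen.

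The first 4 results drew attention because the effect of 2C9.G2 differed between media by an F test: Pdpr (adjusted p = 0.0173), Dhx8 (adjusted p = 0.0203), St6galnac2 (adjusted p = 0.0237) and Ankrd41 (adjusted p = 0.0317), within 10 genes in all. Of these Pdpr, a gene of pyruvate dehydrogenase control, stood at 4.15 in TPO against 0.25 in SCF and 0.48 in SCF+TPO, and passed with the SCF+TPO labels exchanged (adjusted p = 0.00705). Only the 2 TPO IgG arrays stood apart, with a mean of -2.88 against 0.10 to 1.44 in the other groups. Dhx8, St6galnac2 and Ankrd41 had opposite signs in TPO and SCF+TPO as labelled (Ankrd41 against SCF+TPO IgG arrays none of which was well above background) and did not pass with the labels exchanged (adjusted p = 0.455, 0.116 and 0.108). For St6galnac2 and Dhx8 this rests on the probe used. The second St6galnac2 probe had nearly the same value in TPO and SCF+TPO, and the other Dhx8 probe did not fall in TPO.

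A signal in data outside the comparisons also stood out: each of the 6 SCF+TPO columns of the deposited value table followed the scanner file of the other antibody, with r of 0.992 or more, against 0.009 to 0.138 with its own. For the other 10 columns r with the own file was 0.991 to 0.999. Blank cells disagreed with the scanner flags in 30482 of 203052 cells (15%) as named and in 112 once exchanged, so an exchange of IgG and 2C9.G2 in the table or in the scanner files is a candidate explanation that had what it needs. Which of the records is wrong cannot be told apart. If the scanner files were, effects in SCF+TPO would be expected to have r below 0 with those of the other media. Here r was -0.035 with TPO (7 of 100 relabelings as large) and -0.014 with SCF (34 of 100), too weak to decide. Exchanged labels gave 168 genes averaged over media against 5. Slide 2 held the 2 TPO IgG arrays and 2 arrays of SCF+TPO 2C9.G2, so slide enters the effects in TPO and SCF+TPO with opposite signs. Slide alone could thus lower r with TPO or, with labels exchanged, raise the count, so neither value decides between the records. No biological explanation was tested.

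Dim genes were lower with 2C9.G2 in SCF and TPO. The 75th percentile scaling, 1 constant per array, was argued against, as the dimmest minus the brightest class within an array, which it leaves alone, differed with 2C9.G2 by -0.649 ± 0.069 (SE) in TPO and -0.476 ± 0.11 in SCF, although the planned test did not decide (-0.196 in TPO with quantile normalization). That 2C9.G2 lowers dim signal in every medium was argued against by SCF+TPO, where the median of the dimmest class was -0.005 and would be small with either sign. A fall of all dim signal on the array may explain the pattern in TPO: 288 olfactory and vomeronasal receptor genes, which blood cells hardly express, had a median of -0.433, inside the range of random lists of like brightness (-0.496 to -0.254). In SCF their median of -0.661 lay beyond the random lists (-0.505 to -0.251), on the lower side, so whether the same holds there cannot be told apart, and an effect of the antibody on transcripts stays open as untested, as each of these groups had its own slide.

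The 3 arrays of TPO with 2C9.G2 varied more than those of other groups, with a median SD of 0.671 log2 units against 0.351 to 0.486 and array weights of 0.54 to 0.63 against 0.78 to 1.44. The planned test counted against cells of another type in some of the cultures, as 1 of 7 marker lists, MHC class II and dendritic genes (SD 0.868), passed the 95th percentile of random lists (0.788). It does not exclude them, since the random lists came from the same variable arrays. Mast cell and erythroid lists reached percentiles 89.7 and 88.1. Array 2 was lowest for the MHC class II list (-1.74 against -0.22 and -0.26) and for the erythroid list (-0.82 against -0.06 on each other array). Loss of transcripts at random before hybridization cannot be told apart: the planned count met its bar, as 797 genes were at least 3 log2 units lower on 1 array than on both others, against 372 to 404 in other groups of 3, but any larger spread would give this, and genes as far higher were as many (806, a ratio of 0.989 against 1.074 to 1.42). Noise of spots or hybridization cannot be told apart either, since deviations of 2 probes of 1 gene correlated at 0.076, within the range of other groups (0.033 to 0.087, 5296 gene pairs). No biological explanation was tested.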

How the results depend on the processing

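The runs with exchanged labels, with the value table matched to the scanner files, with slide as a block for lists and for IgG groups only, and of lists in IgG groups only, were added after the results were seen; the others were planned. For the genes named, 6788 of 7895 values kept their side of the threshold, 976 lost the call, 131 gained one, 0 called values reversed, and 120 of the 6788, without a call, changed sign. Many of the 7895 values belong to genes without a call to lose, so the share kept does not measure how often calls held. No named gene passed for the antibody in SCF or SCF+TPO, where 519 of 536 and 810 of 810 values kept their side. For the antibody in TPO, 327 of 972 values lost the call, and the 972 include genes without one. Counts below are limma calls, with the number at an unadjusted p under 0.05 beside each 0. Without any effect, a share of 0.05 of the genes tested would be expected at such a p, so these numbers alone are no sign of an effect. Where no reason is given the cause was not tested.

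For 2C9.G2 in TPO (94 genes), the count was 34 with quantile normalization (33 of them among the 94), 14 with normexp (10 shared), 23 without a filter, 60 with the stricter filter, 4 in the deposited value table, 12 with replicate number as a block, 0 (1526) with only the arrays of TPO, where fewer arrays gave the spread, 24 with trend and robust moderation, 12 with array weights and 35 genes over every probe. With slide as a random block it was 1099, with a negative consensus correlation (-0.168). Slide and group mostly coincided, so a block with such a correlation could not separate them. The larger counts with this block, here and below, are therefore no support for any call. Of single genes, Pdpr kept its call in 26 of 27 alternatives, Dhx8 in 22, A26c3 in 21, Rnf103 in 19, Npm2 in 17 and Ankrd41 in 13.

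For 2C9.G2 in SCF (1 gene), the count was 3 with quantile normalization, 0 (1008) with normexp, 2 without a filter, 0 (1422) with the stricter filter, 0 (1379) in the value table, 297 with slide as a random block, 0 (1612) with the replicate block, 0 (1976) with only the arrays compared, 0 (1455) with trend and robust moderation, 20 with array weights and 3 over every probe. In SCF+TPO (1 gene) it was 0 with normexp (787), the stricter filter (630), the value table (704, also when matched to the scanner files), slide as a fixed block (963), the replicate block (756) and only the arrays compared (1003), and 2 without a filter and with array weights.

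Averaged over media (5 genes), it was 3 with quantile normalization, 0 (1332) with normexp, 32 in the value table, 1 in the matched table, 33 with slide as a random block, 1 with the replicate block, 2 with trend and robust moderation and 168 with exchanged labels. For the F test between media (10 genes), it was 0 (1450) with normexp, 6 with the stricter filter (all 6 shared), 1 with the deposited values, 2 with the matched ones, 849 with slide as a random block, 0 (1797) with the replicate block, 6 with trend and robust moderation, 17 with array weights and 5 with exchanged labels (4 shared).

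Between TPO and SCF (241 genes), the count was 137 in the value table, 1342 with slide as a random block, 118 with only the arrays compared and 60 in IgG groups only, where fewer arrays were compared. For SCF+TPO against SCF (437), it was 247 without a filter, 2658 with slide as a random block, 1155 with array weights and 732 in IgG groups only. For SCF+TPO against TPO (53), it was 83 with normexp, 26 without a filter, 35 with the stricter filter (all 35 shared), 378 with slide as a random block, 11 with the replicate block, 15 with only the arrays compared, 101 with trend and robust moderation, 8 in IgG groups only and 0 (1218) in IgG groups with slide as a fixed block. Socs2, Ncam2, Enah, Stxbp6, Gem, Thbd and Pcdh7 kept their calls in every alternative run between TPO and SCF. Gem, for SCF+TPO against TPO, kept its call in 28 of 29, but Dusp6 in 8 and Dusp4 in 5. Replicate numbers did not pair the arrays (36 pairs across groups, r from -0.036 to 0.023).

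With an estimated correlation, 0 lists passed for 2C9.G2 in SCF, TPO, SCF+TPO or on average, and 4 of 9 between SCF+TPO and TPO. With quantile normalization 0 passed in TPO and on average. With normexp 0 passed in SCF, TPO and on average, and 1 in SCF+TPO. With the deposited values 1 passed in TPO and 1 on average, and with slide as a fixed block 1 in SCF+TPO. The correlation of antibody effects was -0.054 for TPO and SCF+TPO without a filter, and 0.03 for SCF and TPO with the replicate block.

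Leaving out 1 array at a time moved most counts, and where a group kept 1 array that array was assumed to vary like the other groups. In TPO the count ran from 14 (without TPO IgG 1) to 66 (without SCF+TPO 2C9.G2 1). It was 18 without TPO IgG 2, 21, 29 and 40 without SCF IgG 2, 1 and 3, 39 without either SCF 2C9.G2 array, 29 and 36 without TPO 2C9.G2 1 and 2, 52, 32 and 35 without SCF+TPO IgG 1, 2 and 3, and 37 and 33 without SCF+TPO 2C9.G2 2 and 3. In SCF it ran from 0 (without SCF IgG 2 or 3, SCF 2C9.G2 1 or 2, TPO IgG 1 or 2, TPO 2C9.G2 2 or 3, SCF+TPO IgG 3 or SCF+TPO 2C9.G2 1, 1159 to 1930 unadjusted) to 4 (without SCF+TPO IgG 1), with 3 without SCF IgG 1 or SCF+TPO 2C9.G2 2 or 3. In SCF+TPO it ran from 0 (without SCF+TPO IgG 2 or 3 or any SCF+TPO 2C9.G2 array, 646 to 852 unadjusted) to 2 (without SCF IgG 1 or 3, SCF 2C9.G2 1 or 2, TPO 2C9.G2 1 or SCF+TPO IgG 1). Averaged over media it ran from 0 (without SCF 2C9.G2 1, 1866 unadjusted) to 12 (without TPO IgG 2), with 3 without SCF IgG 1 or 3 or SCF+TPO IgG 2 and 8 without TPO 2C9.G2 3. For the F test it ran from 0 (without TPO IgG 1, 1696 unadjusted) to 12 (without SCF IgG 1), with 4, 6, 3 and 2 without SCF IgG 2, SCF 2C9.G2 2, TPO IgG 2 and SCF+TPO 2C9.G2 3.

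Between TPO and SCF it ran from 123 (without TPO IgG 2) to 269 (without TPO 2C9.G2 3), with 133 without SCF 2C9.G2 2 and 143 without TPO IgG 1. Between SCF+TPO and SCF it ran from 110 (without SCF 2C9.G2 2) to 475 (without TPO 2C9.G2 1), with 236 without SCF 2C9.G2 1, 224 and 205 without SCF IgG 2 and 3, 229, 257 and 210 without SCF+TPO IgG 1, 2 and 3, and 231 and 197 without SCF+TPO 2C9.G2 1 and 2. Between SCF+TPO and TPO it ran from 12 (without SCF+TPO 2C9.G2 1 or 2) to 73 (without TPO 2C9.G2 2), with 14 without SCF+TPO 2C9.G2 3, 21 and 15 without TPO IgG 1 and 2, and 22, 28 and 15 without SCF+TPO IgG 1, 2 and 3. Lists passing ran from 0 to 2 in SCF, 0 to 3 in TPO, 0 to 3 in SCF+TPO, 0 to 6 on average, 9 to 12 between TPO and SCF, 10 to 14 between SCF+TPO and SCF and 7 to 10 between SCF+TPO and TPO. Signal over background limits the dim genes, whose antibody effect turned with normexp in SCF and TPO.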

Other observations

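The splits of samples below were planned before the results were seen, and the comparison with exchanged labels was added after.

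For 2C9.G2 in SCF+TPO, 3 arrays against 3 give 10 splits, too few for a share under 0.05. The real split gave 1 gene, the highest other 0, and 1 of 10 splits gave as many. For lists the real split gave 3, the highest other 3, and 2 of 10 gave as many.

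For 2C9.G2 averaged over media, 1 of 100 splits within media, the real one, gave as many genes as the real 5 (highest other 3). In SCF and in TPO the IgG and 2C9.G2 arrays were on different slides, which the other splits mix. The splits thus cannot tell antibody from slide. The exchange of all SCF+TPO labels, itself a split within media but not among the 100, gave 168 genes, which points to a structure of the samples, and the count of 5 holds only if the scanner files are right. For lists 18 of 100 gave as many as the real 2 (highest other 7), so chance was not excluded for the SRCAP, TIP60 and MLL list or for oxidative phosphorylation.

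Between TPO and SCF, 1 of 100 splits gave as many genes as the real 241 (highest other 7) and 3 of 100 as many lists as the real 10 (highest other 10). Between SCF+TPO and SCF, 1 of 100 gave as many genes as the real 437 (highest other 109) and 2 of 100 as many lists as the real 12 (highest other 12). Between SCF+TPO and TPO, 1 of 100 gave as many genes as the real 53 (highest other 12) and 4 of 100 as many lists as the real 9 (highest other 10). For each of these 6 counts, a share under 0.05 of the splits drawn gave as many. Splits of arrays leave slide aside, which follows the media in most groups, so they cannot tell medium from slide.

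With the SCF+TPO labels exchanged, 168 genes passed for 2C9.G2 averaged over media, against 5 as labelled, and Dhx8 (-1.26 ± 0.145) and Pdpr (1.31) were among them.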
